A study of Rattus norvegicus with 16 samples.

How the data were processed

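Kidney cortex RNA was measured by RNA sequencing in 16 rat libraries, 4 each from young females, young males, old females and old males. Per the labels' protocols, total RNA was extracted with an RNeasy Micro kit and libraries were made with a stranded TruSeq mRNA kit. The submitters' processing notes name the genome build Rnor_6.0 and edgeR 3.8.6, without saying what each was used for. The aligner, the counting program and whether counting used strand are not given in the sources used here, so genes that overlap on opposite strands and members of near-identical gene families are reported as uncertain.

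The counts per gene were deposited by the authors as a table of 32623 genes by 16 libraries, per the file headers, and were used as deposited. Beside them, the authors deposited RPKM values for the same genes and libraries. These equal each count scaled by the library's total and the listed gene length plus 1 (largest relative difference 5.6e-16), so they carry no further information and entered no test. The authors also deposited 4 pairwise gene lists with log2 fold changes and false discovery rates (adjusted p-values), per the file headers, which hold only genes with an absolute log2 fold change over 1 and a false discovery rate under 0.05. The raw counts repeated in those lists equal the count table. Gene symbols and Ensembl identifiers were taken from the count table. The listed start and end of a gene span less than its summed length for 70.5% of genes, so no positions other than chromosomes are given.

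The labels give each library an identifier that starts with DS or OP, with no explanation. All young libraries carry DS, and the old libraries carry both (old female replicates 1 and 2 and old male replicates 1, 2 and 3 carry OP). Sex labels were checked by the counts of genes on chromosome Y. No pair of libraries in a group agreed within sampling noise, with a chi-square per degree of freedom of 6.29 to 50.0 over genes with at least 20 counts, so no library is a copy of another in its group. This does not show whether the libraries are separate animals, and all 16 were treated as separate samples.

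Genes were kept with edgeR's filterByExpr for the 4 groups, which left 14390 genes holding 99.93% of the counts, and 18233 genes were not tested. Libraries were scaled with TMM factors. Counts were fitted with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) in 1 model with a mean for each group, so that all 16 libraries share 1 estimate of the spread (biological coefficient of variation 0.13). The contrasts were old against young males, old against young females, young males against young females, old males against old females, and the age-by-sex contrast, which is the age change in males minus that in females. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene passed at an adjusted p under 0.05. Every adjusted p printed for a gene comes from this edgeR test, except those given for other settings, which come from the fit of that setting. CPM are counts scaled to a common total per library with the same factors, given as mean ± SD.

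Before the data were examined, 42 gene lists were fixed from general knowledge, covering pathways of the kidney and of DNA sensing, markers of cell types and neighbouring tissues, and checks of labels and tissue quality. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and again with an estimated correlation, and with fry. The 40 lists with at least 2 tested members entered the adjustment over lists. Counts of members past the threshold are given over all tested genes and, where so stated, adjusted over the list alone.

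The genes to be named were also fixed by a rule before the data were examined. In each pairwise comparison these are the 10 genes with the largest fold in each direction among those that passed, with a proper symbol, a mean CPM of at least 2 in 1 of the groups, and all 4 libraries of a group above all 4 of the other. The rule adds the 6 largest in each direction in the age-by-sex contrast, up to 4 members of each list with the smallest p among those that passed (up to 2 where none did), and Cgas and Sting1, which the count table holds under its older symbol Tmem173. A gene with 0 counts in a group is given as a lower bound of the fold, with 3 counts over the group's 4 libraries as the floor. With 1 to 3 counts, the ratio of CPM is given with its exact 95% interval. Fitted fold changes of such genes depend on the prior count. Intervals and floors cover counting error only.

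Alternatives were RLE and upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a filter of CPM at least 1 in 4 libraries, only the 2 groups compared, stricter thresholds, the replicate number as a block, the identifier prefix as a covariate, DS libraries alone, and each library left out in turn. A fit with each library's mean log2 CPM of the inner medulla genes as a covariate was added after the data were seen. Where the groups compared differ in this score, the covariate also lowers precision, so calls can be lost although the values stay. The main fit was tested on simulated counts with each gene's mean over all 16 libraries and the real library sizes, in which 200 genes were changed among 14390. For old against young males it called 91% of the genes changed 2-fold, for old against young females 85.1%, for young males against young females 85.1%, for old males against old females 86.6%, and for the age-by-sex contrast 73.1%. At 1.5-fold these shares were 53.7%, 52.2%, 53.7%, 56.7% and 20.9%. Fewer genes were changed in the simulation than passed in any real contrast, and evenly up and down. The shares therefore need not hold for the real contrasts, and the simulation cannot test the scaling of the libraries.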

Results

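RNA was sequenced from kidney cortex of young and old rats of both sexes, with 4 libraries in each of the 4 groups. The labels give age only as young or old and state that no treatment was given. The title names diabetic kidney disease, but no label marks a library as diabetic, and the genotype label (Homo) is not explained. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples, which may be technical. Total counts per library (in units of 1e+06) were 11.57 to 14.74 in young females, 13.42 to 20.27 in young males, 14.27 to 17.05 in old females, and 10.83 (replicate 4) to 35.96 (replicate 2) in old males.

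Eif2s3y and Kdm5d, on chromosome Y, had 0 counts in all 8 female libraries. In the 8 male libraries Eif2s3y was at 78.6 to 91.3 CPM and Kdm5d at 26.3 to 32.4 CPM, so no sex label was contradicted. Xist, which marks the inactive X chromosome, is not in the count table. Old males stood apart on the first principal component, which held 47.5% of the variance, and young males on the second, with 23.6%. Old male replicate 4, the shallowest library and the only DS library among the old males, lay farthest out (86.3 on the first component against 57.4 to 72.7 for the other old males). Mitochondrially encoded genes took 18.8 ± 0.522% of counts in young females, 22.3 ± 2.57% in young males, 20.4 ± 1.44% in old females and 17.5 ± 1.83% in old males (SD, n = 4).

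**Figure D1:**
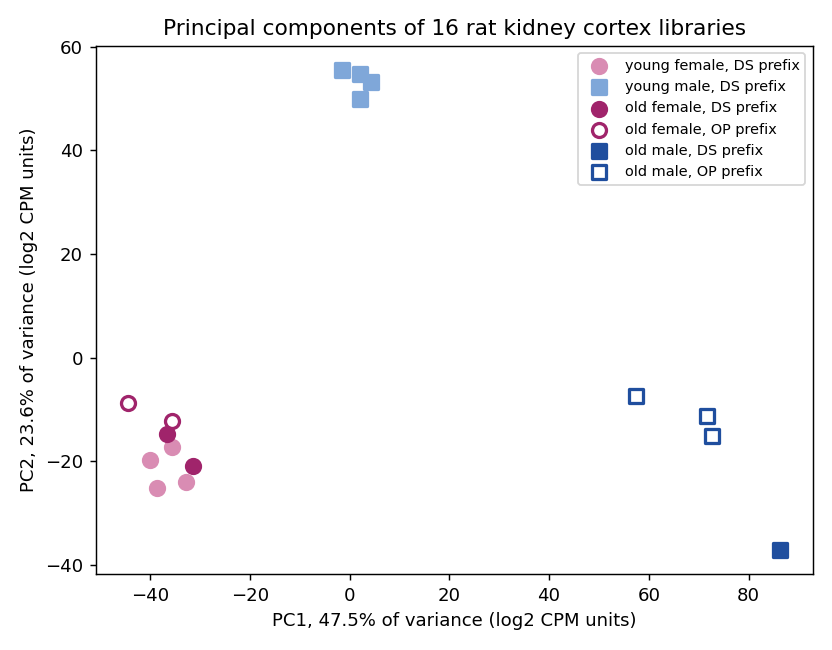
Principal components 1 and 2 of log2 CPM for the 16 libraries, 1 point per library, colored by group, with open symbols for the OP identifier prefix. Old males lie at 57.4 to 86.3 on the first component and young males at 49.9 to 55.5 on the second, while young and old females lie close together.

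The first question was how the male kidney cortex differs with age. Old males carried far more mRNA of injury genes than young males. Havcr1, which encodes the proximal tubule injury marker KIM-1, stood at 179 ± 25 CPM in old and 3.77 ± 1.32 CPM in young males (SD, n = 4), a 46.7-fold difference. Lcn2, which encodes the injury marker NGAL, rose from 3.98 ± 0.144 to 107 ± 30.9 CPM, and Spp1, which encodes osteopontin, from 296 ± 80.2 to 12600 ± 3150 CPM. Among the genes that fell were the steroid hydroxylase Cyp2c11, from 118 ± 15.5 to 3.51 CPM (log2 fold change -4.91, SE 0.466, adjusted p = 8.85e-06), and the organic anion transporter Slco1a1 (-3.62, SE 0.551). Of 14390 genes tested, 3644 were higher and 3545 lower in old males, of which 1522 and 674 differed at least 2-fold, and 46.3% had all libraries of a group above those of the other, against 2.86% by chance. The even split depends on the scaling, since with library totals alone 7849 were higher and 1329 lower. Age is also partly tied to the identifier prefix, since all young males carry DS and 3 of the 4 old males OP. With the prefix as a covariate 5812 of the 7189 calls (80.8%) were kept.

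The cGAS-STING list holds a few sensors of DNA in the cytosol and many genes of the signaling around them. In old males 14 of 20 tested members were higher, 2 lower and 4 did not pass (14 and 2 adjusted over the list alone). Tmem173 (ENSRNOG00000042137, chromosome 18), the older symbol of Sting1, which encodes the adaptor STING, rose from 2.53 ± 0.633 to 8.96 ± 0.56 CPM (log2 1.83, SE 0.236, adjusted p = 8.84e-06). Ikbke, a kinase that acts beside TBK1, rose by 1.44 (SE 0.168), the nuclease gene Dnase2 by 1.11 (SE 0.116) and Samhd1 by 1.06 (SE 0.133). Cgas (ENSRNOG00000046191, chromosome 8), which encodes the DNA sensor itself, was low in every group and stood at 0.808 ± 0.103 CPM in old and 0.409 ± 0.326 CPM in young males (log2 1.01, SE 0.385, adjusted p = 0.0377). The lower members, named after their values were seen, were Enpp1 (-0.40), whose enzyme degrades the messenger cGAMP, and Rnaseh2b (-0.25). As a set the list ranked higher in old males (camera adjusted p = 0.000367, and adjusted p = 0.0208 with an estimated correlation), with a median of 0.558. Immune cell markers moved in the same libraries, with macrophage genes higher for 17 of 17 (median 1.46), T and NK cell genes for 18 of 18 (2.6) and B and plasma cell genes for 9 of 10 (4.38). The Cgas call held in 9 of 21 other settings, with log2 values of 0.69 to 1.61 and adjusted p of 0.00236 to 0.528. It was lost without any one of young male replicates 1, 3 and 4 and old male replicates 1, 2 and 3, with no low-count filter, with only the 2 groups compared, with the prefix as a covariate (0.96), in DS libraries alone (0.69) and with the inner medulla score as a covariate (0.98).

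Interferon-stimulated genes, which cells switch on after interferon signaling, were higher in old males for 34 of 41 tested members and lower for 0 (34 and 1 adjusted over the list alone), with Lgals3bp at 1.69 (SE 0.126) and Irgm at 1.57 (SE 0.133). Camera gave adjusted p = 1.84e-10, and adjusted p = 0.167 with an estimated correlation. Of the NF-kappaB and inflammasome genes 23 of 25 were higher and 0 lower (24 and 1 adjusted over the list alone), such as the adhesion gene Icam1 (1.70, SE 0.127), and the set held with an estimated correlation (adjusted p = 0.0488). All 20 antigen presentation genes were higher (20 adjusted over the list alone, adjusted p = 0.0203 with an estimated correlation), including the proteasome subunit Psmb9 (1.89, SE 0.126) and the class II gene RT1-Ba (1.56, SE 0.113), whose reads may be shared among RT1 genes. Of 21 complement genes 20 were higher and 1 lower (20 and 1 adjusted over the list alone). C4b, which may share reads with C4a, reached 411 ± 121 CPM from 9.49 ± 1.63 CPM, and Cfi, the complement factor I gene, rose by 5.19 (SE 0.325). The complement set gave adjusted p = 2.19e-09, and adjusted p = 0.0617 with an estimated correlation.

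Markers of lymphocytes and macrophages were higher in old males. All 18 tested T and NK cell genes rose (18 adjusted over the list alone), among them the T cell receptor subunit Cd3e (2.71, SE 0.26) and the surface protein gene Cd5 (3.17, SE 0.232). The set held with an estimated correlation (adjusted p = 0.0203). B and plasma cell genes rose for 9 of 10 (9 adjusted over the list alone, adjusted p = 0.0203 with an estimated correlation). Ighm, the heavy chain of IgM, stood at 212 ± 66.7 CPM against 10.1 ± 2.04 CPM, and Jchain rose by 4.36 (SE 0.294), although immunoglobulin genes can share reads. All 17 macrophage and monocyte genes rose (17 adjusted over the list alone), such as Cd68 (1.69, SE 0.164), with adjusted p = 1.27e-08 for the set and adjusted p = 0.0976 with an estimated correlation. Of the 12 neutrophil genes only 2 could be tested, with Csf3r higher (2.00, SE 0.316) and Mmp9 lower (-2.18, SE 0.382). Il24, a cytokine gene with 0 counts in young males, was at least 153-fold higher, and Reg3b, a secreted lectin gene that may share reads with Reg3g, had a count ratio of 697 (125 to 27600).

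Of 22 injury genes 18 were higher in old males and 2 lower (19 and 2 adjusted over the list alone), including Gpnmb (4.42, SE 0.27) and Anxa2 (1.93, SE 0.104), and the set held with an estimated correlation (adjusted p = 0.0335). Fibrosis and matrix genes were higher for 28 of 35 (29 adjusted over the list alone), with the protease inhibitor Timp1 at 2.97 (SE 0.186) and Vim, the vimentin gene, at 2.15 (SE 0.153). That set had adjusted p = 0.203 with an estimated correlation. Senescence and secretory genes were higher for 14 of 23 and lower for 2 (15 and 3 adjusted over the list alone), with adjusted p = 0.0617 with an estimated correlation. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 7.78 ± 1.41 to 31.5 ± 1.39 CPM. Cell cycle genes were higher for 18 of 21 (18 adjusted over the list alone, adjusted p = 0.252 with an estimated correlation), such as the proliferation marker Mki67 (1.61, SE 0.257). Immediate early genes, which can respond to handling of tissue, were higher for 10 of 18 (11 adjusted over the list alone, adjusted p = 0.418 with an estimated correlation), with Klf6 at 2.06 (SE 0.215). Btg2 (1.19) no longer passed in DS libraries alone (0.62).

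All 36 nuclear oxidative phosphorylation genes fell in old males (36 adjusted over the list alone), by -0.54 in the median, such as the complex I subunit Ndufa10 (-0.70, SE 0.0612). All 13 mitochondrially encoded genes fell as well (13 adjusted over the list alone), by -0.70 in the median. The sets gave adjusted p = 2.19e-15 and 4.21e-06, and adjusted p = 0.167 and 0.315 with an estimated correlation. Fatty acid oxidation genes were lower for 25 of 34 and higher for 0 (26 and 0 adjusted over the list alone, adjusted p = 0.127 with an estimated correlation), with the dehydrogenase Acadm at -1.21 (SE 0.0726). Organic anion and cation transporters were lower for 15 of 21 (15 adjusted over the list alone, adjusted p = 0.196 with an estimated correlation), and drug and steroid metabolism genes for 21 of 32 (23 adjusted over the list alone, adjusted p = 0.0683 with an estimated correlation). Cat, the catalase gene, fell from 2580 to 864 CPM, and Miox, an inositol oxygenase of the proximal tubule, from 3430 to 1010 CPM. Antioxidant genes went both ways (6 higher and 11 lower of 23, 6 and 11 adjusted over the list alone), and camera did not call the set (adjusted p = 0.0514).

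Markers of the nephron segments did not move alike. Proximal tubule genes fell for 14 of 24 and rose for 7 (14 and 7 adjusted over the list alone, adjusted p = 0.0273 for the set and adjusted p = 0.502 with an estimated correlation), and those of its S3 segment fell for 10 of 11 (10 adjusted over the list alone, adjusted p = 0.357 with an estimated correlation), with Acy3 at -2.01 (SE 0.22). Podocyte genes were higher for 2 and lower for 6 of 15, and endothelial genes lower for 6 of 15 (2 and 6, and 4, adjusted over the list alone). Camera called no difference for thick ascending limb, distal convoluted tubule, principal cell, intercalated cell and inner medulla genes, whose set medians lay between -0.308 and 0.0671. Fibroblast, pericyte and mesangium genes were higher for 7 of 15 and lower for 2 (8 and 2 adjusted over the list alone, adjusted p = 0.38 with an estimated correlation). With library totals alone in place of TMM factors the median of all genes was 0.323 (-0.00278 with TMM), so that list medians less than this below 0, here those of the thick ascending limb, inner medulla, podocyte and endothelial lists, would lie near or above 0 on that scale.

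**Figure D2:**
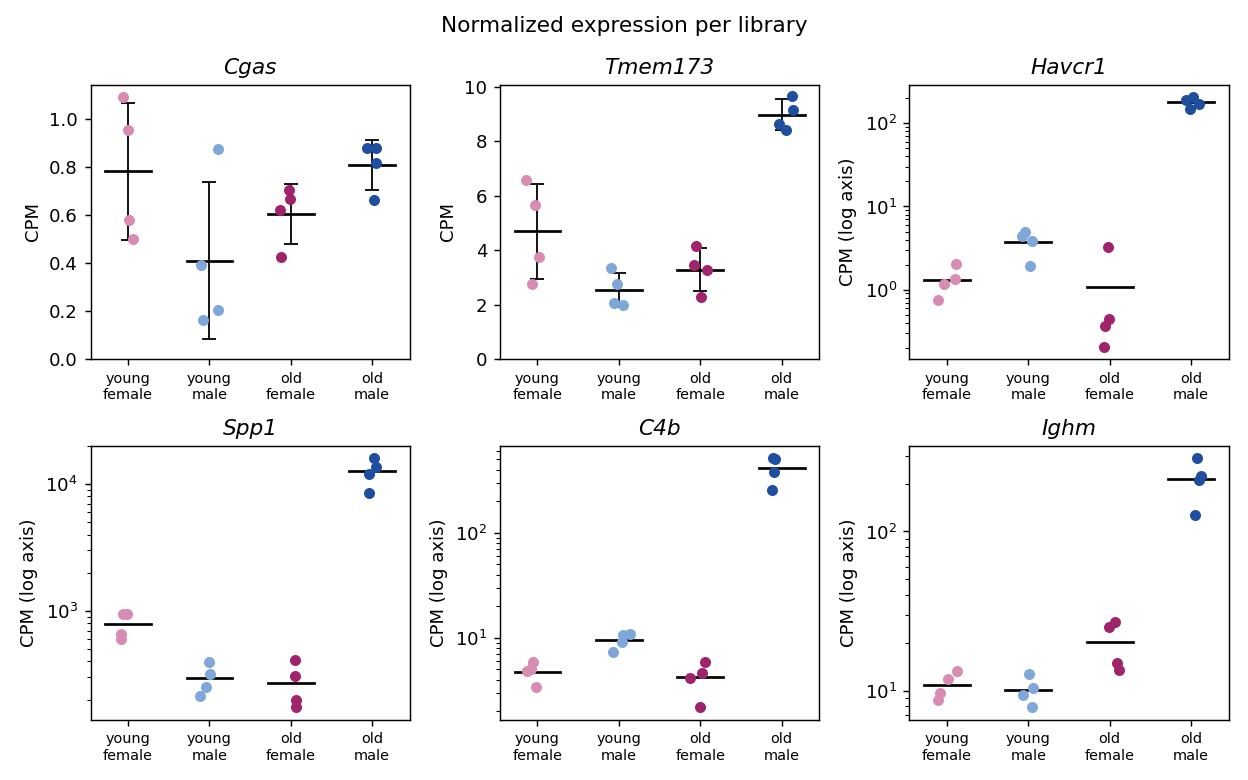
CPM of 6 genes in each of the 16 libraries, 1 point per library, with horizontal lines for group means and, on the linear axes of Cgas and Tmem173, bars for SD (n = 4). The axes of Havcr1, Spp1, C4b and Ighm are logarithmic, and their old male libraries lie above all others.

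The matching comparison in females asked whether the cortex of old females differs from that of young females. Fewer genes passed, with 366 higher and 456 lower in old females, of which 79 and 181 differed at least 2-fold, and 11.1% showed no overlap between the groups against 2.86% by chance. Pnoc, which encodes a neuropeptide precursor, rose from 0.259 ± 0.127 to 9.81 ± 2.09 CPM (SD, n = 4, log2 5.21, SE 0.286, adjusted p = 3.89e-08). Cyp24a1, whose enzyme breaks down active vitamin D, rose from 16.3 ± 12.8 to 262 ± 65.3 CPM (adjusted p = 5.81e-05), and the growth factor gene Fgf10 rose by 2.70 (SE 0.301). Cyp4a2, a fatty acid hydroxylase gene that may share reads with Cyp4a3, rose from 671 ± 294 to 2510 ± 480 CPM, and Rimbp2 and Scg2 rose by 2.38 (SE 0.184) and 1.89 (SE 0.238). Fetub, which encodes a fetuin, stood at 58.8 ± 16.4 CPM against 16.8 ± 4.1 CPM. Igf1, the insulin-like growth factor gene, fell by 2.08 (SE 0.265). Cgas (-0.37, adjusted p = 0.639) and Tmem173 (-0.52, adjusted p = 0.239) did not pass. With the inner medulla score as a covariate Tmem173 was at 0.13 and did not pass either, and its adjusted p over all settings was 0.0776 to 0.907.

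Of 9 tested inner medulla genes, which are markers of tissue below the cortex, 3 were lower in old females and 6 did not pass (6 lower adjusted over the list alone), with a median of -1.07. Camera gave adjusted p = 0.00316, and adjusted p = 0.628 with an estimated correlation. Slc14a2, the urea transporter of the inner medullary collecting duct, was at 3.94 ± 4.55 CPM in old and 42.5 ± 17.3 CPM in young females. The mean log2 CPM of the list was 4.76 to 5.96 in young females, and in old females it was 3.30 and 3.46 in the OP libraries and 4.72 and 4.76 in the DS libraries. As this score differs between young and old females, adding it as a covariate also lowers precision. With it as a covariate 42 of the 822 calls were kept, and the counts were 32 higher and 15 lower. Without young female replicate 1 they were 132 and 182, and in DS libraries alone 168 and 105. Pnoc, Cyp24a1, Fgf10, Cyp4a2, Rimbp2, Scg2, Fetub and Igf1 passed in all of these settings. Many other calls were not stable. Of the 822, 311 (37.8%) were kept without young female replicate 1. With the identifier prefix as a covariate 468 (56.9%) were kept, and with only the 2 groups compared 480 (58.4%).

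Several other gene groups differed between old and young females, and the members named in this paragraph lost their calls with this score as a covariate. Interferon-stimulated genes were lower for 15 of 41 and higher for 0 (26 and 0 adjusted over the list alone), with adjusted p = 1.44e-14 for the set and adjusted p = 0.628 with an estimated correlation. Gbp2, a guanylate-binding protein gene, was lower in old females (-0.99, SE 0.189). Matrix genes were lower for 8 of 35 (2 higher and 15 lower adjusted over the list alone, adjusted p = 0.628 with an estimated correlation), such as Fn1 (-1.21, SE 0.215), which encodes fibronectin. Cell cycle genes were lower for 5 of 21 (9 adjusted over the list alone, adjusted p = 0.628 with an estimated correlation), such as Top2a, a topoisomerase of dividing cells (-2.41, SE 0.557). Fatty acid oxidation genes were higher for 4 of 34 (5 adjusted over the list alone) and antioxidant genes for 3 of 23 (6 adjusted over the list alone), the latter including Gpx1, a glutathione peroxidase gene (0.70, SE 0.122). Those sets had adjusted p = 0.628 with an estimated correlation each. With the inner medulla score as a covariate Gbp2, Fn1, Top2a and Gpx1 no longer passed, at -0.92, -0.84, -3.19 and 0.72, so that the values moved less than the calls. In DS libraries alone Gbp2 (-0.78), Fn1 (-0.85) and Top2a (-2.55) did not pass either, and Top2a was also lost without young female replicate 2 (-2.26) or old female replicate 4 (-2.17).

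Intercalated cell genes, from cells of the collecting duct that secrete acid or bicarbonate, were higher in old females for 6 of 14 (8 higher and 2 lower adjusted over the list alone), including the anion exchanger Slc26a4 (1.05, SE 0.174) and Insrr (0.81, SE 0.138). Distal convoluted tubule genes were higher for 3 of 9 (5 adjusted over the list alone) and podocyte genes for 3 of 15 (5 adjusted over the list alone), such as Cdkn1c (0.75, SE 0.102). The 3 sets had adjusted p = 0.000488, 0.000488 and 0.00393, and adjusted p = 0.628 each with an estimated correlation. Slc26a4, Insrr and Cdkn1c passed with the inner medulla score as a covariate. No list passed in this comparison with an estimated correlation. Injury genes did not move as a set, with 2 of 22 higher, 3 lower and 17 not passed (2 and 3 adjusted over the list alone), and Spp1 fell from 785 to 272 CPM, a call lost with the inner medulla score as a covariate (-1.10 against -1.53). Of the T and NK cell genes 2 of 18 were lower, of the B and plasma cell genes 2 of 10, and of the macrophage genes 1 of 17 was higher and 1 lower (3 lower, 3 higher and 2 lower, and 1 and 1, adjusted over the list alone). The B and plasma cell median was -0.392, or -0.163 with members of at most 3 counts in a group set to the count floor.

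The age-by-sex contrast tested the difference between the sexes directly. The age change differed between males and females for 5563 genes, with 2786 more positive in males and 2777 more negative, of which 1637 and 669 differed at least 2-fold. With library totals alone these were 6677 and 898. The contrast contains the age change in females, in whom the inner medulla score differed between young and old. With that score as a covariate 4168 of the 5563 calls (74.9%) were kept, and Tmem173 passed at 1.83. In the main fit Tmem173 was among the 5563 genes, with an age change 2.34 log2 units higher in males (SE 0.338, adjusted p = 5.92e-05). So were Spp1 (6.94, SE 0.416) and Igf1 (2.62, SE 0.378). Cyp24a1 (-4.16, SE 0.497), Cat (-1.40, SE 0.193) and the membrane protein gene Mlc1 (-4.33, SE 0.866) had a lower age change in males. Cgas did not pass (1.39, SE 0.543, adjusted p = 0.0539), and it passed in 6 of 28 other settings, with adjusted p between 0.00522 and 0.489. Of the 20 cGAS-STING genes 13 were more positive in males and 2 more negative (14 and 2 adjusted over the list alone), and the set held with an estimated correlation (adjusted p = 0.0264). The antigen presentation (0.0294), T and NK cell (0.0247), B and plasma cell (0.0247), NF-kappaB (0.0444) and injury (0.0368) sets also held at those adjusted p with an estimated correlation, all more positive in males. The interferon-stimulated set (39 of 41 more positive, 39 adjusted over the list alone) had adjusted p = 6.33e-16, and adjusted p = 0.0743 with an estimated correlation.

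**Figure D3:**
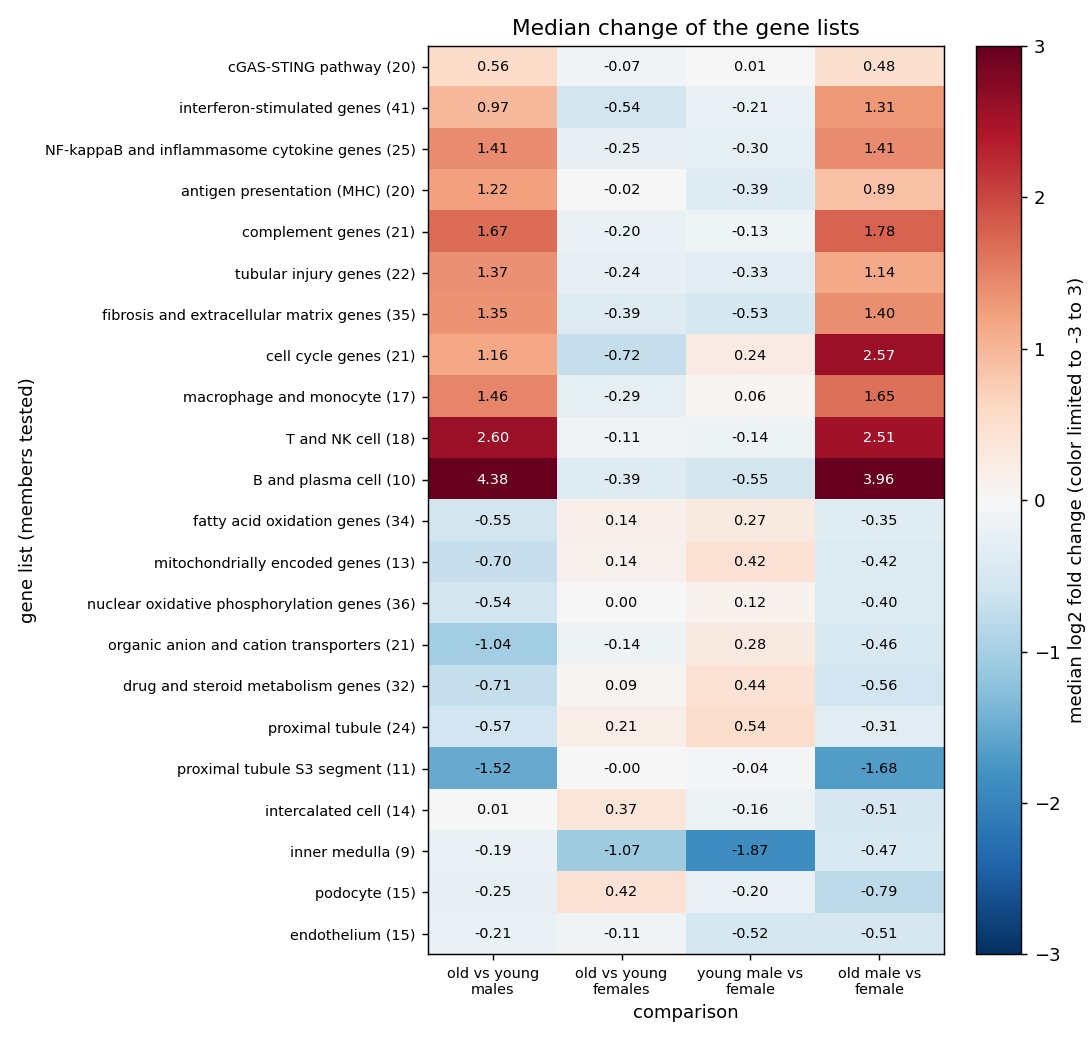
Median log2 fold change of 22 fixed gene lists (rows, with the number of tested members) in the 4 pairwise comparisons (columns), with color limited to -3 to 3. Immune, injury and matrix lists are positive in both comparisons of old males, and with library totals alone the median of all genes is 0.323 (old against young males), -0.056 (old against young females), -0.175 (young sexes) and 0.213 (old sexes), so list medians nearer 0 than this can change sign.

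Genes that changed with age in both sexes were few relative to the male change. Their number is limited by the 822 calls in females, so it is set here beside that expected for independent lists. Of the calls, 131 were higher in both sexes (92.7 expected for independent lists) and 68 lower in both (112 expected), while 213 were higher in males and lower in females (115 expected) and 90 the reverse (90.2 expected). Across genes, which are not independent replicates, the fold changes had a Pearson r of -0.0763 and a Spearman rho of -0.0894. Pnoc was among the genes higher in both sexes, at 7.01 ± 1.07 CPM in old against 0.157 CPM in young males, and Cdkn1a was another (14.3 against 6.13 CPM in females, where the call was lost with the inner medulla score as a covariate at 1.16 against 1.23). With that covariate the counts in both sexes were 15 higher and 7 lower, without young female replicate 1 they were 53 and 31, and without old male replicate 4 those lower in both were 105.

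The sex difference in young rats was asked next. Young males had mRNA that young females lacked almost entirely, such as Cyp2c11 (118 ± 15.5 CPM in males, 0 counts in females, at least 2130-fold higher) and the transporter Slco1a1 (398 against 1.18 CPM, log2 8.39, SE 0.782), both of families whose members can share reads. The organic anion transporter gene Slc22a22 (243 against 0.0807 CPM) and the dehydrogenase gene Dhrs7l1 (9.40, SE 0.8) were among them. Young females had more Slc22a13 (152 against 3.54 CPM) and Slc22a7 (304 against 9.05 CPM), organic anion transporter genes, more Cyp4b1 (-4.83, SE 0.194) and more Stc2 (-6.07, SE 0.273), a stanniocalcin gene. Between young males and young females, 2308 genes were higher and 2266 lower in males, of which 495 and 673 differed at least 2-fold, and 31.1% showed no overlap against 2.86% by chance. With library totals alone 1132 were higher and 4470 lower. Ddx3, which the count table places on chromosome Y, was at least 1180-fold higher in males.

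Fatty acid oxidation genes were higher in young males for 18 of 34 and lower for 6 (19 and 6 adjusted over the list alone), led by Cyp4a2 (10200 against 671 CPM), with adjusted p = 0.000852 and adjusted p = 0.711 with an estimated correlation. Proximal tubule genes were higher for 14 of 24 and lower for 2 (14 and 2 adjusted over the list alone, adjusted p = 0.711 with an estimated correlation), such as the phosphate transporter Slc34a1 (0.98, SE 0.105). Drug and steroid metabolism genes went both ways, 15 higher and 12 lower of 32 (15 and 12 adjusted over the list alone), and camera did not call the set (adjusted p = 0.347), with Gsta2 at 1.58 (SE 0.128) and Gsta3 at -2.63 (SE 0.194), which may share reads. Among sex hormone receptor and growth factor genes 4 of 8 were higher and 2 lower (4 and 2 adjusted over the list alone), without a call of the set (adjusted p = 0.163). They include the prolactin receptor Prlr at 139 against 11.9 CPM, the estrogen receptor Esr1 at 1.92 (SE 0.217) and Igf1 at -1.93 (SE 0.263). Sox9, a transcription factor of tubule repair, stood at 59.7 against 5.95 CPM, and Agt, which encodes angiotensinogen, was higher by 3.25 (SE 0.518). Mitochondrially encoded genes were higher in young males for 8 of 13 (10 adjusted over the list alone) and nuclear oxidative phosphorylation genes for 10 of 36 (10 adjusted over the list alone), with adjusted p = 0.711 and 0.768 with an estimated correlation. The nuclear median was 0.116, which is nearer 0 than the median of all genes with library totals alone (-0.175), so its sign depends on the scaling. Inner medulla genes were lower in the same young males, so their score is partly tied to sex and, as a covariate, also lowers precision. Cgas, for example, moved from -0.952 to -1.221 with it, while its adjusted p went from 0.0908 to 0.313. With the score as a covariate 29.6% of the calls between the young sexes were kept. Cyp4a2 (3.19), Slc34a1 (0.94), Gsta2 (1.89), Gsta3 (-2.49), Prlr (4.57), Esr1 (2.08), Igf1 (-2.10), Sox9 (3.28) and Agt (3.58) passed with it.

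Inner medulla genes were lower in young males for 7 of 9 (1 higher and 7 lower adjusted over the list alone), with a median of -1.87, and Slc14a2 was at 1.5 against 42.5 CPM. Camera gave adjusted p = 0.0137, and adjusted p = 0.711 with an estimated correlation. Several other groups were lower in young males as well. Endothelial genes were lower for 11 of 15 (11 adjusted over the list alone), matrix genes for 14 of 35 (16 adjusted over the list alone) and antigen presentation genes for 8 of 20 (8 adjusted over the list alone), with Vwf, the von Willebrand factor gene, at -2.34 (SE 0.173), the proteoglycan gene Dcn at -1.81 (SE 0.184) and RT1-Db1 at -0.80 (SE 0.122). These 3 sets had adjusted p = 0.711, 0.768 and 0.711 with an estimated correlation. Of the cGAS-STING genes 4 were higher and 2 lower (4 and 2 adjusted over the list alone). Tmem173 was lower in young males (-0.89, SE 0.251, adjusted p = 0.0121) and Cgas did not pass (-0.95, SE 0.413, adjusted p = 0.0908). With the inner medulla score as a covariate Tmem173 moved to -0.06 and no longer passed, and the counts were 742 genes higher and 665 lower. Tmem173 was also lost without young female replicate 1 (-0.70), and Cgas passed without young male replicate 2 (-1.54) and with library totals alone (-1.13).

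**Figure D4:**
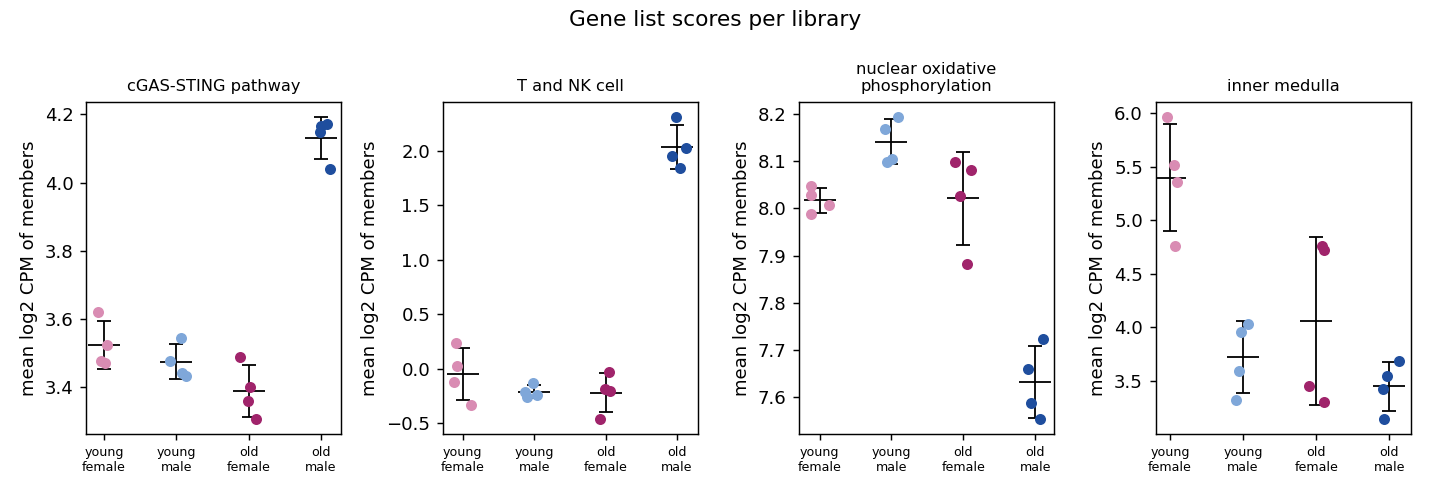
Mean log2 CPM of the members of 4 gene lists in each of the 16 libraries, 1 point per library, with lines for group means and bars for SD (n = 4). Old males lie highest for the T and NK cell list (1.84 to 2.31) and lowest for the nuclear oxidative phosphorylation list (7.56 to 7.72), and young females lie at 4.76 to 5.96 for the inner medulla list.

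The last comparison set old males against old females. Havcr1 stood at 179 ± 25 CPM in old males and 1.07 ± 1.46 CPM in old females (SD, n = 4, log2 7.44, SE 0.409, adjusted p = 1.44e-09), with old female replicate 1 at 3.25 CPM. Lcn2 was higher by 5.18 (SE 0.213), Spp1 by 5.53 (SE 0.324), C4b by 6.62 (SE 0.277) and Ighm by 3.40 (SE 0.256). Slc22a7 (1.69 against 214 CPM) and Slc22a13 (0.845 against 127 CPM) were lower in old males, as they were in young males, and Sds, a serine dehydratase gene, was lower by -6.02 (SE 0.608). Between old males and old females, 3664 genes were higher and 3431 lower in males, of which 1518 and 752 differed at least 2-fold, and 44.6% showed no overlap against 2.86% by chance. In DS libraries alone, which hold 1 old male and 2 old females, the counts were 2132 and 2134, and with library totals alone they were 6066 and 1831.

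Of the 20 cGAS-STING genes 17 were higher in old males than in old females and 1 lower (17 and 1 adjusted over the list alone), with adjusted p = 4.22e-05 for the set and adjusted p = 0.0144 with an estimated correlation. Tmem173 was higher by 1.45 (SE 0.227, adjusted p = 5.47e-05), although in DS libraries alone its difference of 1.14 did not pass, and Cgas did not pass (0.43, SE 0.354, adjusted p = 0.33). Zbp1, a sensor of Z-form nucleic acids, was higher by 2.26 (SE 0.277), and Nfkb1, an NF-kappaB subunit gene, by 1.15 (SE 0.0955). Interferon-stimulated genes were higher for 39 of 41 (40 adjusted over the list alone, adjusted p = 0.078 with an estimated correlation), with Rtp4 at 2.69 (SE 0.195). All 18 T and NK cell genes and 9 of 10 B and plasma cell genes were higher (18 and 9 adjusted over the list alone), both with adjusted p = 0.0144 with an estimated correlation. Injury genes were higher for 19 of 22 and lower for 2 (19 and 2 adjusted over the list alone, adjusted p = 0.044 with an estimated correlation). Cell cycle genes were higher for 19 of 21 (19 adjusted over the list alone, adjusted p = 0.078 with an estimated correlation), and Top2a stood at 11.3 CPM in old males against 0.613 CPM in old females.

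Nuclear oxidative phosphorylation genes were lower in old males than in old females for 35 of 36 (35 adjusted over the list alone), with a median of -0.403, and podocyte genes were lower for 12 of 15 (12 adjusted over the list alone), such as the slit diaphragm gene Nphs1 (-1.45, SE 0.214). Both sets had adjusted p = 0.251 with an estimated correlation. Endothelial genes were lower for 9 of 15 (10 adjusted over the list alone, adjusted p = 0.251 with an estimated correlation) and intercalated cell genes for 11 of 14 with 1 higher (13 and 1 adjusted over the list alone, adjusted p = 0.463 with an estimated correlation). Prlr was higher in old males (1.43, SE 0.304), but in DS libraries alone, which hold a lone old male, the difference was -0.44. With library totals alone the median of all genes in this comparison was 0.213, against 0.0114 with TMM.

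Of the 2308 genes higher in young males than in young females, 833 were also higher in old males than in old females, 388 were lower and 1087 were not called. Of the 2266 lower in young males, 982 stayed lower, 429 were higher and 855 were not called. With the inner medulla score as a covariate the genes higher and lower in males at both ages were 361 and 455, and in DS libraries alone those higher at both ages were 490. Independent lists would share 588 higher and 540 lower genes, and would oppose in 550 and 577. The sex difference itself changed with age, by the age-by-sex contrast, toward females for 1160 and toward males for 110 of the male-biased genes, and toward males for 968 and toward females for 193 of the female-biased genes. The genes were chosen by the young libraries that this contrast uses again, which alone favors a change toward the other sex. Across genes, the sex differences in young and old rats had a Pearson r of 0.426 and a Spearman rho of 0.174. Prlr (139 against 11.9 CPM in young and 40 against 15 CPM in old rats), Cyp4a2 (6180 against 2510 CPM in old rats) and Slco1a1 (31.7 against 1.1 CPM in old rats) were higher in males at both ages and among the 1160. Single old libraries overlapped for Prlr, with 14.1 CPM in the lowest old male and 20.3 CPM in the highest old female, and for Slco1a1, with 0.165 CPM in 1 old male against 0.846 to 1.38 CPM in old females.

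The authors' 4 deposited lists hold 1974 genes for old against young males, 291 for old against young females, 1002 for young males against young females and 2019 for old males against old females. All of their genes that were tested here had the same direction in the same counts, and 99.1%, 77.3%, 97.9% and 99.4% also passed here.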

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

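The tests of the splits, of tubule share, of blood, of library scaling and of proximal tubule share were chosen after the result was seen, while those of inner medulla, depth, identifier prefix and mitochondrial genes were written before. Of 274 sets of 4 samples examined for a single sample far from the other 3, 13 held one, against 13.7 expected by chance. Old male replicate 4 lay below its group for renin-angiotensin genes (mean log2 CPM 3.75 against 4.66 to 4.81), for thick ascending limb genes (5.87 against 7.01 to 7.21) and for Slc22a22 (3.55 CPM against 56 to 59). Old male replicate 1 stood apart for tubular injury genes (6.61 against 6.85 to 6.86) and podocyte genes (4.36 against 3.96 to 4.02), and old male replicate 2 for Slc14a2 (0.0488 CPM against 0). Old male replicate 2 is the deepest library, and this value lies below the floor of 3 counts, so it can reflect depth alone. In old females, replicate 1 stood apart for Havcr1 (3.25 CPM against 0.207 to 0.449) and intercalated cell genes (6.18 against 6.62 to 6.68), and replicate 2 for sex hormone receptor genes (2.49 against 2.82 to 2.83). In young females, replicate 1 stood apart for renin-angiotensin genes (5.14 against 4.96 to 4.99), replicate 2 for Lcn2 (4.59 CPM against 3.7 to 3.83) and replicate 3 for Slc22a13 (117 CPM against 160 to 168). The genes of chromosome Y in young female replicate 2 (-3.11 against -3.11) differ only beyond the printed digits, since all have 0 counts.

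The age change differed between males and females, by the test of the difference itself, for 5563 genes. Among those named, the largest log2 differences toward males were in Il24 (10.58), Cd79b (9.31), Postn (8.02), Il19 (7.63), Cr2 (7.09) and Spp1 (6.94), and Tmem173 (2.34) was also among them. Il24, Cd79b, Postn, Il19 and Cr2 had 0 to a few counts in 1 or more groups, so their fitted values depend on the prior count. The largest toward females were in Cyp1a1 (-5.83), Cyp8b1 (-5.20), Mlc1 (-4.33), Cyp24a1 (-4.16), Gc (-3.97) and Anxa13 (-3.94).

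The same contrast set 23 gene lists apart, given here as the median log2 difference of the age change in males from that in females. More positive in males were the cGAS-STING (0.619), interferon-stimulated (1.46), NF-kappaB (1.52), antigen presentation (1.12), complement (2.23), tubular injury (1.56), matrix (1.9), senescence (0.683), cell cycle (2.1), immediate early (0.551), fibroblast (0.512), macrophage (1.58), T and NK cell (2.81) and B and plasma cell (4.13) lists. More negative in males were the fatty acid oxidation (-0.736), mitochondrially encoded (-0.856), nuclear oxidative phosphorylation (-0.555), renin-angiotensin (-0.926), organic ion transporter (-1.28), drug and steroid metabolism (-0.618), antioxidant (-0.557), proximal tubule (-0.866) and S3 segment (-1.56) lists. Only the cGAS-STING, NF-kappaB, antigen presentation, tubular injury, T and NK cell and B and plasma cell lists kept their call with an estimated correlation. All these differences contain the age change in females, in whom the inner medulla score differed between young and old. The lists were not tested with that score as a covariate.

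The grouping of libraries was tested by all 35 ways to split the 8 libraries of each pairwise comparison into sets of 4, each fitted alone. In each of the 4 comparisons 1 split, the real one, gave as many genes as it did. The real splits gave 7007 genes for old against young males, 567 for old against young females, 4325 for young males against young females and 6822 for old males against old females, and no other split gave more than 1 gene. A large difference between the real groups widens the spread within every other split, so few calls could arise there. The splits thus add little to the calls themselves. They do not address what sets the groups apart, such as the identifier prefix. For the age-by-sex contrast 1 of 100 splits, again the real one, reached its 5563 genes. The highest of the others gave 4044, and the median was 0. That highest split kept both old groups whole, but labeled young female replicates 2, 3 and 4 as male together with young male replicate 1. It thus reversed most of the young sex labels and is not close to the real split. With young labels reversed and old labels kept, the contrast comes near to the sum of the sex differences at both ages. Such splits carry real sex differences, so the rank of the real split adds little to the age-by-sex calls.

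T cell and NK cell genes were higher in old males than in young males, by a median of 2.6, and the lowest old male library (mean log2 CPM 1.84) lay above the highest of the other 12 (0.235). A lower share of tubule cells as the whole cause would raise podocyte and endothelium genes alike, but their median was -0.23 over 30 genes. Animals of the OP identifier group as the cause would raise these genes in OP libraries of old females, where the OP minus DS median was -0.313, and 17 of 18 genes passed with the prefix as a covariate. Blood left in the pieces would raise the haemoglobin genes, whose median was -0.265 with 0 of 4 past the threshold. An infiltrate of lymphocytes in old males, or lymphoid tissue in their pieces, could give this pattern, and neither was tested.

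Respiratory chain genes were lower in old males than in young males, for 36 of 36 nuclear oxidative phosphorylation genes. The scaling of the libraries does not account for all of this, because with library totals alone 20 were still lower, with a median of -0.213 beside an all-gene median of 0.323. A lower share of proximal tubule cells alone would lower their markers together, but 7 of 24 proximal tubule markers rose while 14 fell. Leaving out the mitochondrially encoded genes, after which 36 were lower (median -0.541), decides nothing on fewer reads of a few mitochondrial genes, because fewer such reads would raise the share of all other genes. A change within tubule cells with age is left open and may act beside a change in cell shares, which these data cannot separate.

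Inner medulla genes were higher in young females than in young males. A second list of inner medulla markers, fixed before its values were looked at, had a median of -1.6 in young males, with 9 of 11 lower, and -1.07 in old females, with 5 lower and 1, Tspan8, higher (adjusted p = 0.00795). More inner medulla in the pieces from young females is therefore a candidate explanation that fits. A difference in sequencing depth does not, since 7 of 9 genes stayed lower after every library was thinned to the smallest total. A sex difference in the expression of these genes within the same tissue could give the same values and was not tested.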

How the results depend on the processing

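All alternatives but the inner medulla covariate were chosen before the data were examined. The RLE and upper-quartile factors, limma-voom, both filter alternatives and the replicate block left all counts of genes within 1.5 times. Replicate numbers were treated as names, since deviations of same-numbered libraries correlated at -0.131 to 0.191 and the best-matched number was the same in only 4 of 16 cases. Between the young sexes, however, replicates 1 (0.123) and 4 (0.191) best matched their own number. On the fourth principal component young female and young male replicate 4 lay at -22.9 and -20.7, against 4.45 to 12.2 for the other young libraries. Per the file headers, the identifiers of both these replicate 4 libraries also carry higher numbers than those of the other young libraries. A factor shared by libraries of the same number is not excluded and was not tested. With the replicate number as a block the higher and lower counts were 2333 and 2250 (young males against young females), 3677 and 3457 (old males against old females), 3649 and 3596 (old against young males) and 389 and 448 (old against young females), and 5653 genes passed in the age-by-sex contrast. With library totals alone the counts were 1132 and 4470 (young sexes), 6066 and 1831 (old sexes) and 7849 and 1329 (male age), which follows from the all-gene medians of -0.175, 0.213 and 0.323 on that scale. The share of higher calls then went to 20.2% (from 50.5%), 76.8% (51.6%), 85.5% (50.7%), 31.2% (44.5%, female age) and 88.1% (50.1%, age by sex), and with upper-quartile factors to 62.4% for male age and 62.1% for age by sex. A log2 fold change of at least 1 left 495 and 673 (young sexes), 1518 and 752 (old sexes), 1522 and 674 (male age), 79 and 181 (female age), 2306 (age by sex), 30 and 12 (higher and lower with age in both sexes) and 224 and 258 (higher and lower in males at both ages), as a stricter rule must. An adjusted p under 0.01 left 1491 and 1409 (young sexes), 106 and 113 (female age), 34 and 14 (age in both sexes) and 505 and 599 (males at both ages). The inner medulla score as a covariate, chosen after seeing the data, gave 742 and 665 (young sexes), 32 and 15 (female age), 15 and 7 (age in both sexes) and 361 and 455 (males at both ages). DS libraries alone, which are fewer and hold a lone old male assumed to vary like the other groups, gave 2132 and 2134 (old sexes), 168 and 105 (female age), 58 higher with age in both sexes and 490 higher in males at both ages. The prefix as a covariate gave 299 lower for female age, DESeq2 124 lower with age in both sexes, and only the 2 groups compared 238 higher for female age and 72 higher with age in both sexes. Leaving out 1 library at a time, female age had 132 (without young female replicate 1) to 472 higher and 182 to 571 lower, and age in both sexes 53 to 161 higher and 31 to 105 lower. Other counts stayed within 1.5 times, at 1748 to 2186 and 1861 to 2225 (young sexes), 3264 to 3527 and 3101 to 3450 (old sexes), 3228 to 3579 and 3180 to 3461 (male age), 5031 to 5507 (age by sex) and 686 to 810 and 850 to 1063 (males at both ages). Of the named genes that passed, 4 changed direction in a setting. Aqp2 (0.16) and Foxi1 (0.0914) did so in the young sexes with the inner medulla covariate, where neither passed. Prlr (-0.44) and Akr1b7 (0.64) did so in the old sexes in DS libraries alone, where the values rest on the lone old male. Except where a reason is given here, the cause was not tested. With every library thinned to the smallest total, the counts were 2148 and 2099 (young sexes), 3449 and 3237 (old sexes), 3411 and 3331 (male age), 330 and 383 (female age) and 2594 and 2565 (age by sex).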

Other observations

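Genes of calcium and phosphate handling went both ways in old males, with 5 of 19 higher and 5 lower than in young males (5 and 5 adjusted over the list alone), and camera did not call the set (adjusted p = 0.965). The sodium-phosphate transporter Slc34a2 rose from 74 ± 18.2 to 251 ± 65.8 CPM (SD, n = 4), and the calcium channels Trpv5 and Trpv6 rose by 1.90 (SE 0.282) and 4.26 (SE 0.569). Cyp27b1, whose enzyme makes active vitamin D, rose by 3.33 (SE 0.623), with a wide spread in old males (4.85 ± 4.04 CPM). The main proximal phosphate transporter Slc34a1 fell from 3140 ± 312 to 1690 ± 130 CPM and the Klotho gene Kl by 0.30 (SE 0.104). In old females Cyp24a1 rose, while Slc34a1 (0.21), Trpv5 (0.51) and Cyp27b1 (-2.05) did not pass. The age change differed between the sexes for Slc34a2 (2.29, SE 0.286), Slc34a1 (-1.10, SE 0.148), Cyp27b1 (5.38, SE 1.44) and Trpv5 (1.39, SE 0.405).

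Glucose handling genes were higher in old than in young males for 9 of 27 and lower for 12 (9 and 12 adjusted over the list alone), and camera did not call the set (adjusted p = 0.166). The glucose transporters Slc5a2 and Slc2a2 rose by 1.52 (SE 0.36) and 1.11 (SE 0.156), and Slc5a1, the transporter of the later tubule, fell by 0.88 (SE 0.254). Khk (-1.58, SE 0.134) and Slc2a5 (-1.63, SE 0.177), of fructose use, and Fbp1 (-1.08, SE 0.105) and Pck1 (-1.71, SE 0.367), of glucose synthesis, fell too. The renin-angiotensin list had 1 of 13 higher and 6 lower in old males (1 and 6 adjusted over the list alone), with adjusted p = 0.0326, and adjusted p = 0.315 with an estimated correlation. Old male replicate 4 lay below the other old males for this list (mean log2 CPM 3.75 against 4.66 to 4.81), and the list median of -0.322 is no farther from 0 than the all-gene median of 0.323 with library totals alone. Its lower members include the peptidase genes Anpep (-1.95, SE 0.221) and Enpep (-0.94, SE 0.0966). Of the sex hormone receptor list 1 of 8 was higher and 4 lower in old males (1 and 4 adjusted over the list alone), and camera did not call the set (adjusted p = 0.228). Prlr fell by 1.78 (SE 0.288) and Esr1 by 1.56 (SE 0.209). Between old males and old females Esr1 (0.13, SE 0.212) did not pass. The age change of Prlr (-2.12, SE 0.433) and Esr1 (-1.79, SE 0.302) differed between the sexes.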
